A study of Mus musculus with 20 samples.

How the data were processed

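RNA from c-Kit-positive, GFP-sorted bone marrow cells was measured on 20 arrays, 300 ng of total RNA each, per the labels' protocols. The values used here are log2 expression values in 1 table of array features by samples, deposited by the authors. They were made with the robust multi-array average (RMA) in Affymetrix Expression Console, per the submitters' processing notes, with no versions given. As a method RMA corrects background, normalizes arrays by quantiles and summarises the probes of a feature, but whether all 20 arrays were normalized together was not given in the sources used here. Such scaling sets the arrays to about the same distribution, so a change of total RNA per cell is not visible. The values ran from 3.64 to 14.23, and all 20 sample columns were matched to their samples by title. The labels gave neither a date nor a batch, so no batch could be tested. Neither background nor detection values were used here, so dim signals were not marked as such, and the number of arrays limits the precision.

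Of 35556 array features, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 had none listed. Symbols of 21698 features were updated by gene ID through a table of RefSeq genes of the assembly GRCm38.p6, which was used for names only. Features with several symbols or none were not named. For 999 genes with more than 1 feature the one with the highest mean over the 20 arrays was used, which left 19938 genes. Some members of the gene lists are not analysed here for that reason. Genes of near-identical families, such as the Mcpt proteases, Tpsb2, Ctla2a and Ctla2b, Ly6 genes and immunoglobulin genes, can share probes, so their single values are uncertain. The genome build behind the array's annotation was not given in the sources used here, so no coordinates are given.

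Samples were grouped by their titles into AE9a high, AE9a low, AE high, AE low and control, with all 4 arrays whose expression label reads control in 1 group. The 8 comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust prior), with p-values adjusted by Benjamini and Hochberg over the genes of each comparison and a threshold of 0.05. AE9a high versus AE9a low was fitted on the 12 AE9a arrays alone, the comparison named in the series' design. The other 7 used all 20 arrays with 5 coefficients. The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were Runx1, Runx1t1 and Kit, and then the 12 highest and 12 lowest changes past the threshold for AE9a high versus AE9a low and for AE9a high versus control, or the 5 and 5 for other comparisons. From each gene list came up to 3 members past the threshold with the largest change or, where none passed, the 2 with the smallest p. Of 28 lists fixed from general knowledge 27 were tested, and the last, sex-linked genes, served only to check the samples. List names are textbook groups, and none was chosen on these samples.

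Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry as alternatives. The preset value assumes nearly independent genes, and the markers of 1 cell type move together between samples, so both results are given. Means of lists per array were compared by exact permutation. The overlap of the 2 high versus low comparisons was set against the number expected of independent lists (the product of both list sizes over the genes tested), and comparisons that share controls against 20 simulations of unchanged groups and against 6 splits of the controls. The steps were tested on simulated data with 200 changed genes among 19938. At a log2 change of 0.5, 83.8% were recovered for AE9a high versus AE9a low and 52.9% for AE high versus AE low, and at a change of 1, 97% and 84.8%. Unchanged genes made up 13 of 200 calls for AE9a high versus AE9a low and 5 of 162 for AE high versus AE low. The set test called none of 20 unshifted sets. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes move together. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

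Alternatives were the samples in the fit, the replicate number as a block, a filter at the median signal, quantile normalization, median centring, an intensity trend with a robust prior, array weights, all features without a choice per gene, only the 3 MIG- controls, and leaving out each array in turn. The covariates of neutrophil and mast cell genes, the fit without 3 arrays, and 4 extra lists (mast granule proteases, basophil genes, monoamine and histamine genes, plasma cell genes) were added after the data were seen. No other deposited table was used here.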

Results

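Gene expression was measured on 20 Affymetrix Mouse Gene 1.0 ST arrays, which read each gene through probes spread along its transcript. Per the labels, fetal liver cells of C57BL/6 embryos at day 13.5 to 14.5 were transduced with a retrovirus that also carries green fluorescent protein (GFP), transplanted into irradiated mice and expanded there for 2 to 3 weeks. Bone marrow cells that carried c-Kit, the receptor found on progenitors and mast cells, were then sorted for the 30% with the lowest or the 30% with the highest GFP. AE is the leukaemia fusion protein AML1-ETO, also called RUNX1-RUNX1T1, which joins the DNA-binding part of RUNX1 to most of RUNX1T1, and AE9a is its shorter splice form. The series held 6 AE9a high, 6 AE9a low, 2 AE high and 2 AE low arrays and 4 controls, of which 3 were titled MIG- and 1 MIG+. The protocols in the labels named only the AE9a vector for every sample and did not say what the signs of the control titles stand for. Nothing in the labels said that the arrays of a group came from separate animals, so p-values measured only the spread between these arrays, which may be technical. Array medians lay between 7.31 and 7.43 on the log2 scale, no pair of arrays held identical values, and the highest correlation between 2 arrays was 0.997. The number of arrays limits the precision, above all for the AE arms with 2 arrays each.

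Both genes whose parts make up the fusion rose with the GFP gate. Runx1, a master regulator of blood formation (array feature 10441003), had a log2 signal of 12.67 ± 0.13 (SD, n = 6) in AE9a high and 12.02 ± 0.31 (SD, n = 6) in AE9a low. Its control signal was 11.42 ± 0.12 (SD, n = 4). Runx1t1, a transcriptional corepressor (feature 10503382), stood at 8.65 ± 0.14 (SD, n = 6) in AE9a high, 8.29 ± 0.10 (SD, n = 6) in AE9a low and 7.23 ± 0.21 (SD, n = 4) in control. In the 2 AE arms the Runx1t1 means were 8.82 for high and 7.84 for low, and the Runx1 means 12.42 and 11.52. AE9a high exceeded AE9a low by 0.64 log2 units for Runx1 (limma, adjusted p = 0.011) and by 0.36 for Runx1t1 (adjusted p = 0.00961), which are ratios of 1.56 and 1.29. AE high exceeded AE low by 0.90 (adjusted p = 0.00935) and 0.97 (adjusted p = 0.0014). Against control, Runx1t1 was higher by 1.42 in AE9a high (adjusted p = 7.21e-08), 1.05 in AE9a low (adjusted p = 2.51e-06), 1.58 in AE high (adjusted p = 9.54e-07) and 0.61 in AE low (adjusted p = 0.00664). The AE low call rested on arrays at 7.56 and 8.13 and was lost without AE low replicate 2, at 0.32 (adjusted p = 0.247), and also in a fit of these 2 groups alone. Runx1 did not pass the test in AE low against control, at 0.10 (adjusted p = 0.778). Kit, which encodes c-Kit itself, was higher in AE9a high than AE9a low by 0.73 (adjusted p = 0.00565) and in AE high than AE low by 1.27 (adjusted p = 0.00773), although all cells had been selected for c-Kit. The calls of Runx1 and Kit in AE high against AE low were lost without AE high replicate 1 or AE low replicate 1, with adjusted p of up to 0.152 and 0.154. These signals sum the mouse gene and whatever part of the transgene its probes can bind, and the species of the transgene's sequence was not given in the sources used here.

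**Figure D1:**
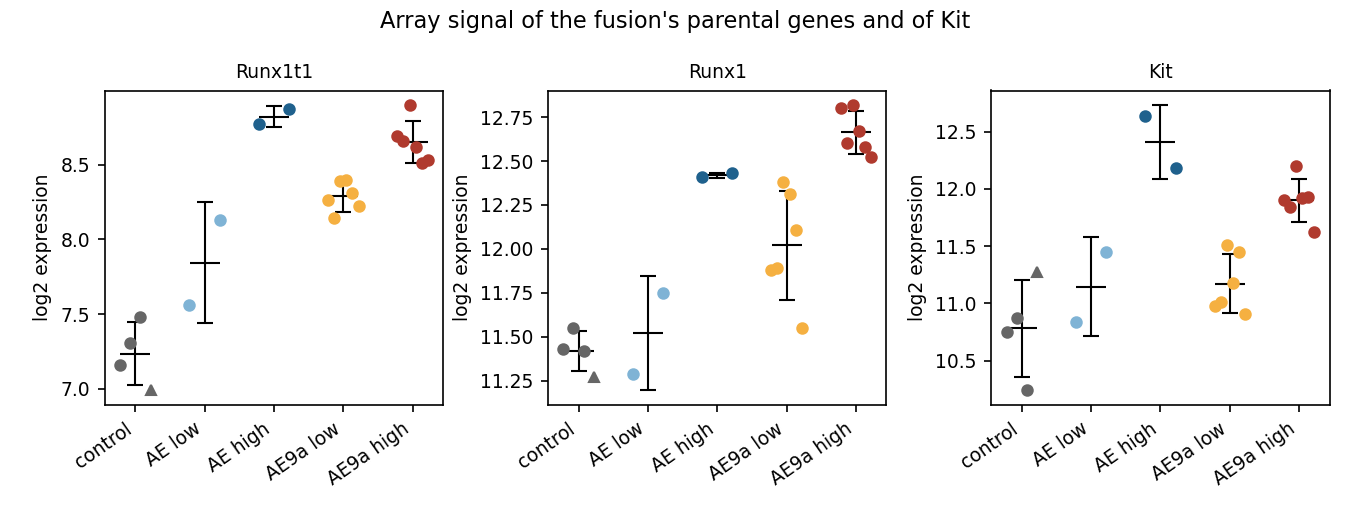
Log2 array signal (vertical axes) of Runx1t1, Runx1 and Kit in each of the 20 arrays, by arm (horizontal axis); dots are single arrays, the triangle is the MIG+ control, and bars give the mean ± SD of each arm. Runx1t1 means run from 7.23 in control to 8.65 in AE9a high and 8.82 in AE high.

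The comparison stated in the series' design set AE9a high against AE9a low, to ask how expression differed with the level of the construct. Genes of mast cells, the histamine-storing cells that depend on c-Kit, led the increase. Mcpt4, a chymase of connective-tissue mast cells, had the highest rise of all genes past the threshold, at 2.63 ± 0.63 log2 units (SE, limma, adjusted p = 0.0233). The tryptase gene Tpsb2 rose by 2.31 ± 0.51 (SE, adjusted p = 0.0171). The IgE receptor chain gene Fcer1a rose by 2.09 ± 0.55 (SE, adjusted p = 0.0338) and the mast cell receptor gene Mrgprb2 by 2.20 ± 0.43 (SE, adjusted p = 0.0114). Among the genes that fell were Igll1 and Ebf1 of early B cells, by 2.65 and 2.35 log2 units, and the MHC class II genes H2-Aa and H2-Ab1, by 2.23 and 2.09.

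In all, 1001 of 19938 genes were higher and 839 lower in AE9a high than in AE9a low, of which 78 and 42 differed at least 2-fold. The homeobox gene Meis2 stood at 10.76 ± 0.53 (SD, n = 6) against 8.49 ± 0.88 (SD, n = 6), and the imprinted gene Mest at 8.14 against 6.18 (adjusted p = 0.000436). The 12 highest rises also held Gask1b (2.09), the receptor gene Mrgpra4 (2.08), Maob, a monoamine-degrading enzyme (1.82), the basophil and mast cell protease gene Prss34 (1.74), the vesicular monoamine transporter gene Slc18a2 (1.72) and the chymase gene Cma1 (1.70). The 12 lowest held the fatty acid desaturase gene Fads2 (-2.18), Qser1 (-2.10), the glutamate receptor gene Gria3 (-1.89), Tifa (-1.81), and Cd74, the invariant chain of MHC class II (-1.76). The same 12 held the pyruvate kinase gene Pklr (-1.64), Strbp (-1.63) and the fatty acid binding protein gene Fabp5 (-1.62). Of the 68 genes named for this comparison that passed the threshold, 42 passed it without each of the 12 arrays in turn. Mcpt4 passed in 8 of the 12 refits (highest adjusted p 0.0585), Cma1 in 6 (0.0811), and Fcer1a and Gria3 in 4 each (0.0804 and 0.0644). Maob, Ebf1, H2-Aa, Qser1 and Tifa passed in 3 each, with highest adjusted p of 0.0992, 0.0744, 0.0703, 0.0853 and 0.0847, and Cd74 in 2 (0.0934). Igll1 lost its call only without AE9a low replicate 1 (0.0508). The total of 1840 fell to 960 without AE9a high replicate 4, 1003 without AE9a low replicate 1, 1017 without AE9a high replicate 1, 1180 without AE9a low replicate 6 and 1187 without AE9a high replicate 2. It reached 2799 without AE9a low replicate 4. Without the 3 arrays farthest from their arm's median on neutrophil genes, AE9a high replicate 6 and AE9a low replicates 1 and 3, 1194 genes passed, and median centring of each array gave 1084 higher and 540 lower. With the mast list mean as a covariate, which correlated with the arm at 0.88, limma called 0 genes, with 915 at an unadjusted p under 0.05.

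Of the 18 measured genes of the mast cell, basophil and eosinophil list, 9 rose, none fell and 9 did not pass the test, with a median change of 0.67 (camera adjusted p = 0.00011). Adjusted over the list alone, 11 rose and 1 fell. With an estimated correlation between genes this list was no longer called (adjusted p = 0.21 with an estimated correlation), and neither was any of the other 26 lists. Only 3 members rose without AE9a high replicate 1, without AE9a high replicate 4 or without AE9a low replicate 1, and 5 without AE9a high replicate 3. In the megakaryocyte list, genes of the platelet-forming lineage, 4 of 17 rose, 1 fell and 12 did not pass (adjusted p = 0.0068, adjusted p = 0.21 with an estimated correlation, 6 rose and 1 fell adjusted over the list alone). Treml1, a platelet granule receptor, rose by 1.32 (adjusted p = 0.000269), and the vesicle trafficking gene Rab27b by 1.19 (adjusted p = 0.0356), a call that held in 3 of 12 refits (highest adjusted p 0.0842). The megakaryocyte list was not called without AE9a high replicate 6. Of 26 stem and progenitor genes 3 rose, namely Kit, the angiopoietin receptor gene Tek by 1.49 (adjusted p = 0.000351) and Slamf1, the CD150 gene, by 1.46 (adjusted p = 0.0192). That list as a whole was not called (adjusted p = 0.89).

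Erythroid genes were lower in AE9a high, with 10 of 27 falling, none rising and 17 not passing the test (median -0.35, adjusted p = 1.5e-08, 12 fell adjusted over the list alone). That call had an adjusted p = 0.34 with an estimated correlation. Hemgn, an erythroid nuclear factor, fell by 1.46 (adjusted p = 0.00289), Alas2, the first enzyme of heme synthesis in red cell precursors, by 1.38 (adjusted p = 0.0179), and the transferrin receptor gene Tfrc by 1.16 (adjusted p = 0.000341). Of the B cell list 2 of 17 fell, Igll1 and Ebf1, with a median of -1.12 (adjusted p = 3.1e-07, adjusted p = 0.39 with an estimated correlation, 3 fell adjusted over the list alone). The number that fell was 0 without AE9a low replicate 1, 7 without AE9a low replicate 3, 8 without AE9a low replicate 2 and 1 without AE9a low replicate 5, AE9a low replicate 6 or any single AE9a high array. Of 15 dendritic cell and antigen presentation genes 3 fell and 12 did not pass, and adjusted over the list alone 9 fell and 1 rose (adjusted p = 8e-05, adjusted p = 0.37 with an estimated correlation).

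Myeloid genes varied widely within both AE9a arms. The mean of the late neutrophil list, genes of secondary granules and mature neutrophils, had a within-arm SD of 1.11 log2 units. In that list 1 of 22 genes fell, Ly6g at -1.59 (adjusted p = 0.0449), a call that held in 3 of 12 refits (highest adjusted p 0.1). The list's median was -0.80 (adjusted p = 0.00024, adjusted p = 0.57 with an estimated correlation). In the primary granule list, enzymes of promyelocytes, none of 12 genes passed limma's test. Its median was -1.42 (adjusted p = 0.0056, adjusted p = 0.56 with an estimated correlation), and Nkg7 (-2.07, adjusted p = 0.124) and Elane, the neutrophil elastase gene (-1.67, adjusted p = 0.168), had its lowest p. Of 26 monocyte and macrophage genes 1 fell, the transcription factor gene Irf8 at -1.02 (adjusted p = 0.0365, called in 3 of 12 refits, highest 0.0862). The list's median was -0.88 (adjusted p = 5e-08, adjusted p = 0.39 with an estimated correlation). Monocyte genes that fell numbered 9 without AE9a low replicate 3 and 7 without AE9a low replicate 4. List means per array were compared between the AE9a arms by exact two-sided permutation over 924 splits. By exact permutation late neutrophil (-0.85, p = 0.21), primary granule (-1.18, p = 0.13), monocyte (-0.90, p = 0.063) and T and NK cell genes (-0.12, p = 0.052) did not pass. The exact permutation gave p = 0.0022, the smallest possible, for mast (0.77), megakaryocyte (0.28), erythroid (-0.45) and dendritic genes (-0.69). B cell genes passed it too (-1.13, exact permutation p = 0.013). These p-values were unadjusted, and the splits did not pair arrays by replicate number.

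Cell cycle genes moved in opposite directions by phase. Of 29 G2/M genes, which act in mitosis, 16 rose, none fell and 13 did not pass (median 0.26, adjusted p = 1.2e-15, 25 rose adjusted over the list alone). Of 27 S-phase genes, which act in DNA replication, 17 fell, none rose and 10 did not pass (median -0.27, adjusted p = 5.9e-15, 23 fell adjusted over the list alone). Both calls were lost at adjusted p = 0.34 with an estimated correlation. The list means per array changed by 0.27 for G2/M (exact two-sided permutation p = 0.0043) and by -0.29 for S-phase genes (exact permutation p = 0.0022). Kif23, a kinesin of cell division, rose by 0.51 (adjusted p = 0.000355), the centromere gene Cenpf by 0.46 (adjusted p = 0.0094) and the spindle gene Nusap1 by 0.44 (adjusted p = 0.00565). Ccne1 and Ccne2, the E cyclins that start replication, fell by 0.96 (adjusted p = 0.017) and 0.52 (adjusted p = 0.00637), and the ribonucleotide reductase gene Rrm2 by 0.61 (adjusted p = 0.00987). The number of G2/M genes that rose was 10 without AE9a high replicate 4. S-phase genes that fell numbered 9 without AE9a high replicate 4 or AE9a low replicate 5, 10 without AE9a high replicate 1 or 3, and 11 without AE9a low replicate 1 or 2.

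Of 29 MYC and ribosome biogenesis genes 14 fell, none rose and 15 did not pass (median -0.28, adjusted p = 1.2e-15, 24 fell adjusted over the list alone), a call lost at adjusted p = 0.34 with an estimated correlation. The mean of this list per array changed by -0.29 (exact two-sided permutation p = 0.0043). The mitochondrial chaperone genes Hspd1 and Hspe1 fell by 0.62 (adjusted p = 0.00728) and 0.48 (adjusted p = 0.0014), and 24 members fell without AE9a low replicate 4. In the DNA repair list 3 of 22 genes fell, Parp1 (-0.33), Msh6 (-0.32) and Xrcc6 (-0.32), and 1 rose (adjusted p = 0.016, adjusted p = 0.39 with an estimated correlation, not called without AE9a low replicate 6). The other 15 lists were not called. Among these, 3 of 10 genes known to be high in leukaemia with the AE translocation rose, Runx1t1, the plakoglobin gene Jup by 1.07 (adjusted p = 0.00376) and the phosphatase gene Ubash3b by 1.04 (adjusted p = 0.000639). Of 12 genes known to be repressed by the fusion none passed limma's test, with the lowest p for the myeloid factor gene Cebpa (-0.53, adjusted p = 0.0582). Of the remaining uncalled lists, Hoxa and Meis genes rose in 1 of 13 cases and T and NK cell genes in 2 of 17 with 1 falling. CDK inhibitors rose in 2 of 6 cases, NF-kB genes in 2 of 19, immediate early genes in 1 of 17 and adhesion genes in 1 of 16. Cholesterol synthesis genes rose in 2 of 16 cases and fell in 1, p53 targets rose in 1 of 22 and fell in 1, and stroma and BCL2 family genes fell in 1 of 15 and 1 of 13. No interferon response gene of 23 and no glycolysis and hypoxia gene of 18 passed limma's test, with the lowest p for Ifi27l2a (0.51, adjusted p = 0.0572) and Pfkp (0.74, adjusted p = 0.0794).

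**Figure D2:**
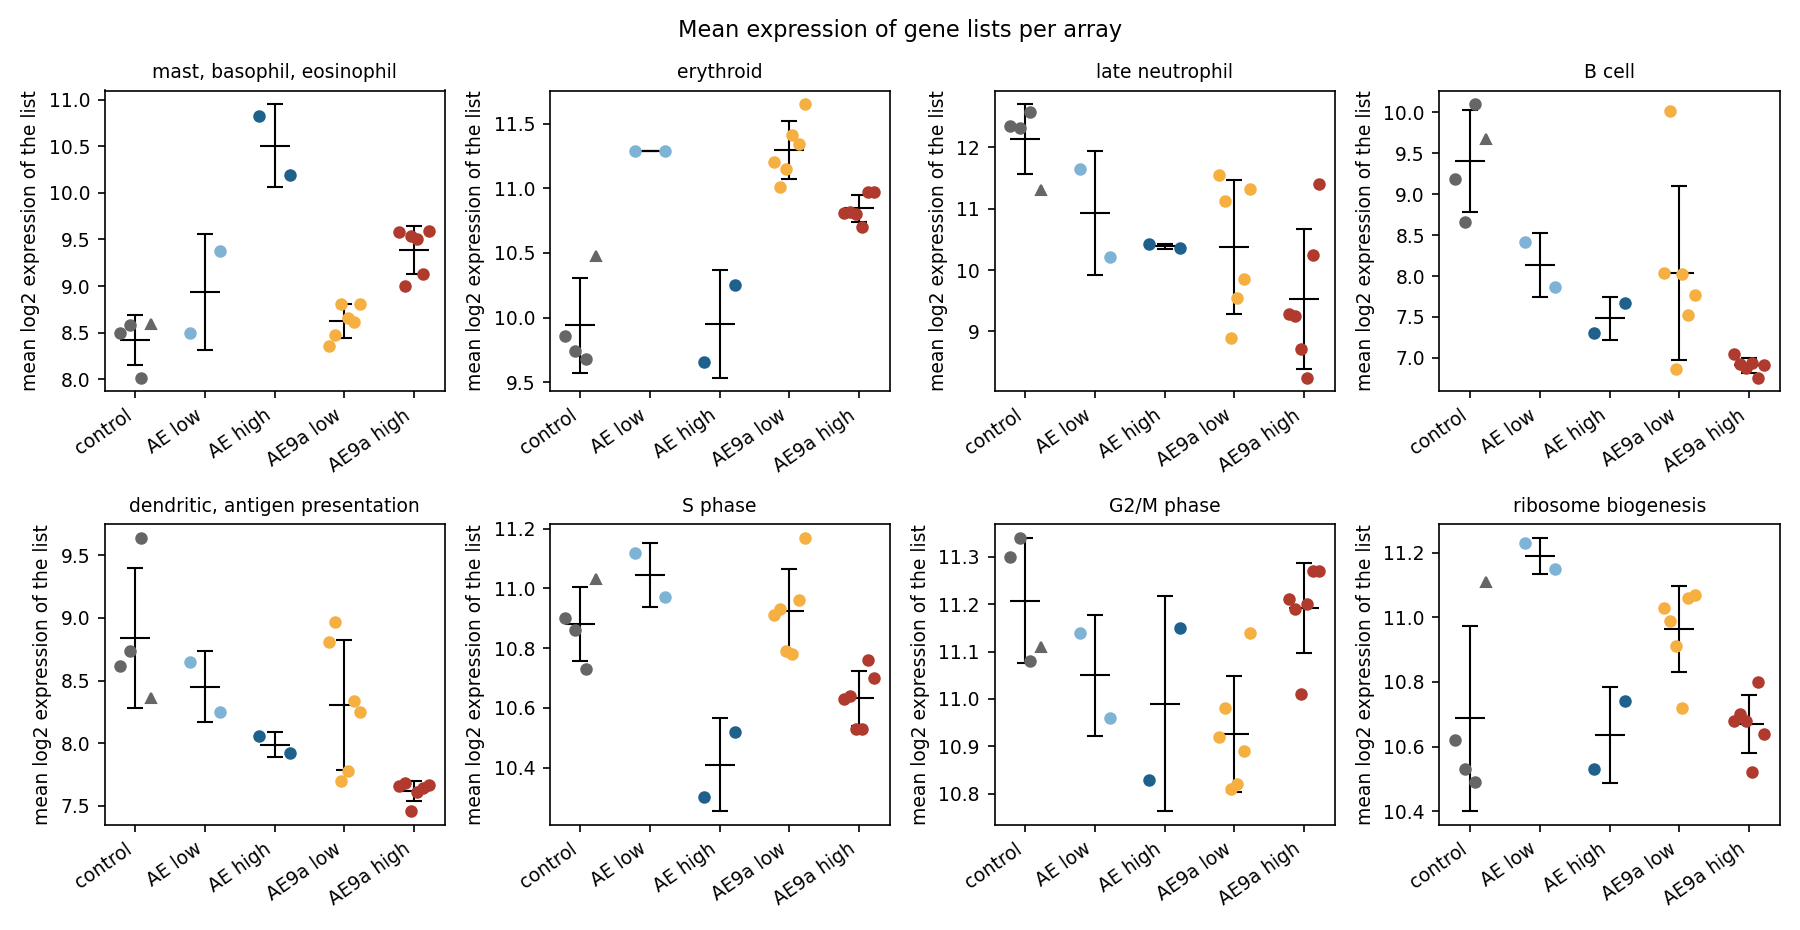
Mean log2 signal (vertical axes) of 8 gene lists in each of the 20 arrays, by arm (horizontal axis); dots are single arrays, the triangle is the MIG+ control, and bars give the mean ± SD of each arm. Late neutrophil means spread within the AE9a arms with an SD of 1.11, and the MIG+ control lies at 11.31 against 12.32 to 12.58 for the MIG- controls.

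The full-length fusion was compared between GFP gates with 2 arrays in each arm, which the 20-array fit allowed by sharing one estimate of the spread. Many red cell genes were lower and some progenitor genes higher in AE high. Tlcd4 fell by 3.78 log2 units (limma, adjusted p = 0.000166), the Rhesus antigen gene Rhd by 2.84 (adjusted p = 0.00029), Hemgn by 2.79 (adjusted p = 0.000194) and the erythroid claudin gene Cldn13 by 2.70 (adjusted p = 0.000392). The related genes Ctla2a and Ctla2b rose by 3.50 (adjusted p = 0.000392) and 3.08 (adjusted p = 5.86e-06). Cyp11a1, a steroid-making enzyme also found in mast cells and basophils, rose by 3.29 (adjusted p = 0.00392), Plxdc2 by 3.23 (adjusted p = 0.000194) and the heparan sulfate enzyme gene Hs3st1 by 3.22 (adjusted p = 1.28e-06). Il6, an inflammatory cytokine gene, rose by 3.02 (adjusted p = 1.2e-06).

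Of 19938 genes 751 were higher and 1317 lower in AE high than in AE low, of which 203 and 125 differed at least 2-fold. Of 27 erythroid genes 18 fell, none rose and 9 did not pass (median -1.24, adjusted p = 1.5e-16, 21 fell adjusted over the list alone), a call lost at adjusted p = 0.13 with an estimated correlation. S-phase genes fell in 24 of 27 cases with 3 not passing (median -0.60, adjusted p = 1.9e-19, adjusted p = 0.12 with an estimated correlation, 26 fell adjusted over the list alone). Among them Ccne1 fell by 1.60 (adjusted p = 0.0049) and the replication licensing gene Cdc6 by 1.00 (adjusted p = 0.00123). No G2/M gene passed limma's test and that list was not called (adjusted p = 0.58). Ribosome biogenesis genes fell in 15 of 29 cases (adjusted p = 1.1e-11, adjusted p = 0.38 with an estimated correlation, 24 fell adjusted over the list alone). DNA repair genes fell in 6 of 22 cases (adjusted p = 0.00067, adjusted p = 0.38 with an estimated correlation, 7 fell adjusted over the list alone). The NF-kB and inflammation list was called with Il6 as its single riser of 19 (adjusted p = 0.0089, adjusted p = 0.47 with an estimated correlation).

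The 4 lists called with the estimated correlation too were higher in AE high. Stem and progenitor genes rose in 12 of 26 cases with 14 not passing (median 0.86, adjusted p = 3.2e-09, adjusted p = 0.045 with an estimated correlation, 14 rose adjusted over the list alone). They were led by the niche factor gene Angpt1 at 2.66 (adjusted p = 0.0154), the homeobox gene Meis1 at 2.27 (adjusted p = 0.00058) and Slamf1 at 2.21 (adjusted p = 0.0144). Genes known to be high in leukaemia with the translocation rose in 4 of 10 cases (median 0.76, adjusted p = 4e-04, adjusted p = 0.013 with an estimated correlation), namely Ubash3b at 1.37, Jup at 1.33, Trio at 1.01 and Runx1t1, itself a part of the fusion. In the megakaryocyte list 3 of 17 genes rose and 1 fell (adjusted p = 0.00049, adjusted p = 0.013 with an estimated correlation, 6 rose and 1 fell adjusted over the list alone). Treml1 stood at 1.68, Clec1b at 1.06 and Gp9 at -0.97. The mast cell, basophil and eosinophil list had a median of 1.52 (adjusted p = 1.1e-07, adjusted p = 0.045 with an estimated correlation), while only Cyp11a1 and the transcription factor gene Mitf (1.59, adjusted p = 0.0428) of its 18 members rose. Of the 47 named genes past the threshold 19 passed it without each array in turn, among them Runx1t1, Meis1, Il6, Treml1, Rhd, Hemgn and Cldn13, and Cyp11a1 did not, at an adjusted p of up to 0.108. The total of 2068 genes fell to 314 without AE high replicate 1 and 561 without AE low replicate 1, and a fit of the 4 AE arrays alone gave 0 genes in limma, with 4083 at an unadjusted p under 0.05.

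**Figure D3:**
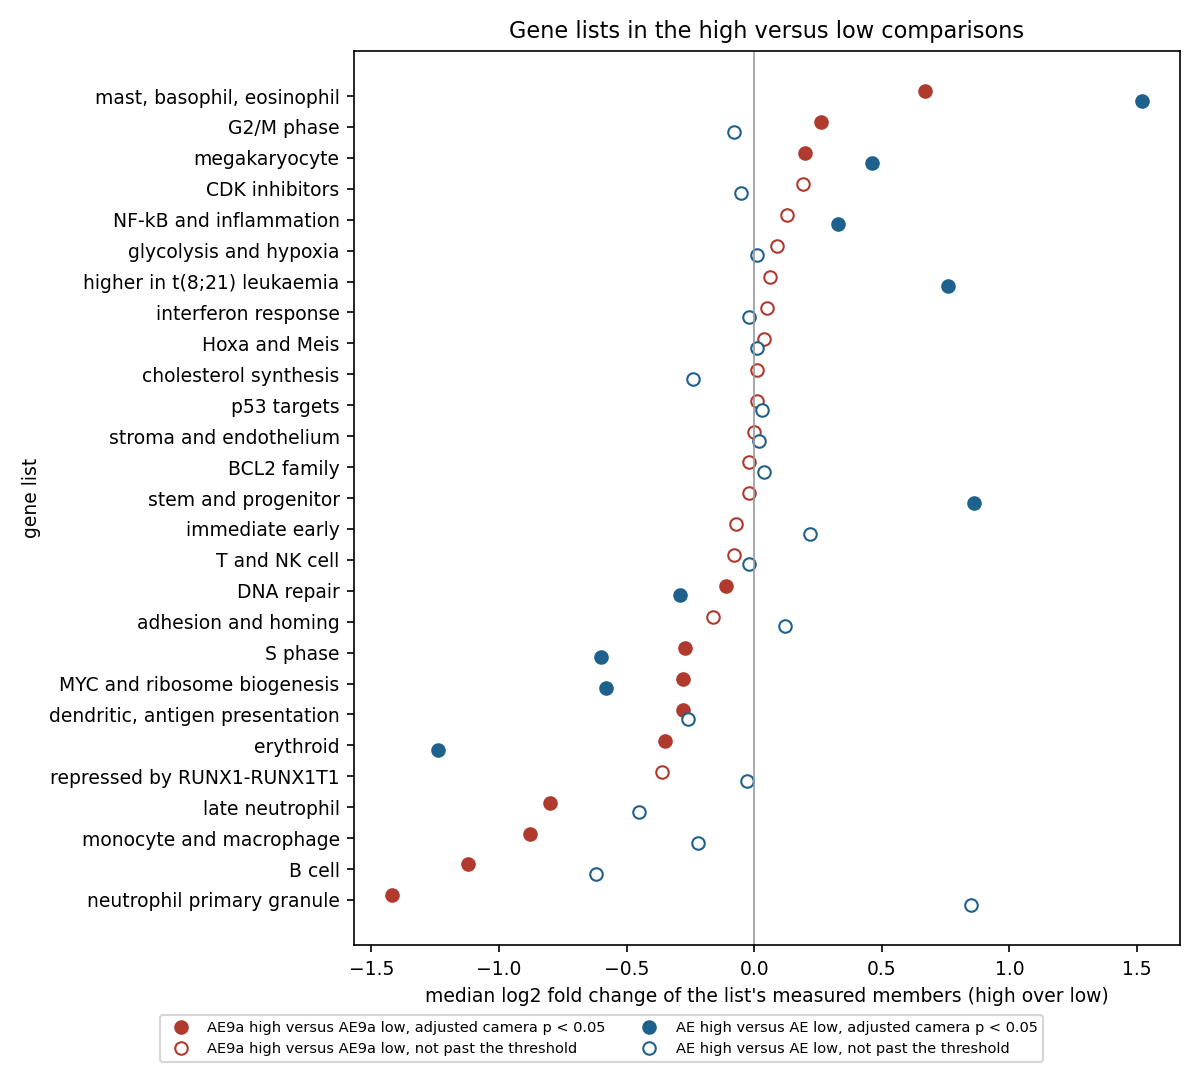
Median log2 change of each of the 27 gene lists (horizontal axis) in AE9a high versus AE9a low and in AE high versus AE low, with lists on the vertical axis; filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not. The mast list lies at 0.67 and 1.52, and the S-phase list at -0.27 and -0.60.

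The change from low to high was then compared between the constructs, as the AE9a difference minus the AE difference. In this test 71 genes were higher and 164 lower, of which 24 and 81 differed at least 2-fold. Tlcd4 (3.09, limma adjusted p = 0.00973), Rhd (2.44, adjusted p = 0.0125), Slc25a21 (2.18, adjusted p = 0.0209), Cldn13 (2.03, adjusted p = 0.0346) and the erythroid membrane gene Tspan33 (2.01, adjusted p = 0.0128) were the 5 highest. Rhd, for example, averaged 11.09 in AE9a high, 11.50 in AE9a low, 8.71 in AE high and 11.55 in AE low. Of the 17 genes named for this contrast that passed the threshold, 5 passed it without each array in turn and 12 did not. At the other end stood Plxdc2 (-3.51, adjusted p = 0.000939), Ctla2a (-3.21, adjusted p = 0.00999), Ctla2b (-2.93, adjusted p = 9.26e-05), Hs3st1 (-2.92, adjusted p = 4.45e-05) and Pecam1, an adhesion molecule of endothelium and platelets (-2.88, adjusted p = 0.0446). Of the stem and progenitor list 4 of 26 genes were lower and none higher (median -0.71, adjusted p = 2.5e-11, adjusted p = 0.03 with an estimated correlation, 8 lower adjusted over the list alone). The median of this list was smaller in size without AE low replicate 1, as given further below. Meis1 stood at -2.13, Procr at -0.97 and Cd48 at -0.91. Of the genes known to be high in leukaemia with the translocation 1 of 10 was lower, Trio at -1.18 (list adjusted p = 0.0012, adjusted p = 0.03 with an estimated correlation, 3 lower adjusted over the list alone). Erythroid genes were higher in 4 of 27 cases (adjusted p = 4.1e-11, adjusted p = 0.38 with an estimated correlation, 15 higher adjusted over the list alone). A further 14 lists were called with the preset correlation and none of them with the estimated one (adjusted p from 0.22 to 0.63). Among these was the mast list, in which none of 18 genes passed (median -0.34, adjusted p = 0.0021, adjusted p = 0.38 with an estimated correlation), and Runx1t1 did not pass either, at -0.61 (adjusted p = 0.144). The total of 235 genes, of 2641 at an unadjusted p under 0.05, was 62 without AE high replicate 1, 72 without AE low replicate 1 and 386 without AE high replicate 2. It was 84 among genes at or above the median signal, 360 in a fit of the fusion arrays alone and 482 with array weights.

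Against the 4 controls, several mast cell genes were much higher in AE9a high, and genes of granulocytes, monocytes and B cells were lower. Mcpt2, a mucosal mast cell protease gene, was higher by 5.86 ± 0.56 log2 units (SE, limma, adjusted p = 6.2e-07). The G protein regulator gene Rgs13 was higher by 5.68 ± 0.29 (SE, adjusted p = 4.01e-09) and the mast cell and basophil receptor gene Cd200r3 by 5.24 ± 0.38 (SE, adjusted p = 5.11e-08). The serotonin-making enzyme genes Ddc and Tph1 were higher by 4.61 and 4.55. Orm1, which encodes an acute-phase protein, changed by -4.65 ± 0.43 (SE, adjusted p = 5.04e-07). The neutrophil surface gene Ly6g changed by -4.29, Igll1 by -4.43 and the immunoglobulin gene Igha by -4.45.

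In AE9a high 4862 genes were higher and 3352 lower than in control, of which 692 and 1007 differed at least 2-fold. Also among the 12 highest were Mcpt1 (4.92), Bex4 (4.91), Pmp22 (4.86), the complement regulator gene Cd59a (4.74), Mpped2 (4.73), the acetylcholine receptor gene Chrna5 (4.64) and Meis2 (4.59). The 12 lowest also held Gpr141 (-4.46), Ebf1 (-4.15), Slco4c1 (-4.03), Ica1 (-4.02), the haptoglobin gene Hp (-3.99), Klrb1f (-3.95), Gca (-3.94) and AA467197 (-3.94). Of the mast cell, basophil and eosinophil list 12 of 18 genes rose, 4 fell and 2 did not pass, and camera did not call it (median 1.21, adjusted p = 0.083). Its eosinophil genes Epx and Prg3 were lower, with means of 7.29 and 6.79 in AE9a high against 10.08 and 7.73 in control. The IgE receptor gene Ms4a2 rose by 4.25 (adjusted p = 3.37e-08), Mcpt4 by 4.01 and Cma1 by 3.64. All 17 B cell genes fell (median -2.35, adjusted p = 2.2e-10, adjusted p = 0.56 with an estimated correlation), as did all 12 primary granule genes (median -2.99, adjusted p = 9e-06, adjusted p = 0.56 with an estimated correlation). So did 20 of 22 late neutrophil genes (median -2.73, adjusted p = 3.2e-10, adjusted p = 0.56 with an estimated correlation) and 22 of 26 monocyte genes (median -1.62, adjusted p = 4.8e-09, adjusted p = 0.56 with an estimated correlation). The same 4 counts were found when adjusted over the list alone. Of the genes known to be repressed by the fusion 7 of 12 fell and 1 rose (adjusted p = 0.0043, adjusted p = 0.56 with an estimated correlation). Elane stood at -2.88, the granulocyte factor gene Cebpe at -2.84 and the G-CSF receptor gene Csf3r at -2.72. Elane is also in the primary granule list, and Cebpe and Csf3r are in the late neutrophil list. The fall of fusion-repressed genes is therefore not separate from that of the myeloid lists. Dendritic cell genes fell in 9 of 15 cases and rose in 2 (adjusted p = 0.00068, adjusted p = 0.56 with an estimated correlation, 11 fell adjusted over the list alone).

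Erythroid genes were higher than control in AE9a high in 21 of 27 cases, lower in 3 and not past the test in 3 (median 1.07, adjusted p = 3.4e-06, adjusted p = 0.56 with an estimated correlation). The membrane skeleton gene Epb42 stood at 2.18, the blood group gene Kel at 2.10 and the anion exchanger gene Slc4a1 at 1.78. S-phase genes fell in 14 of 27 cases and rose in 1 (median -0.19, adjusted p = 1.8e-05, adjusted p = 0.56 with an estimated correlation, 16 fell adjusted over the list alone). Interferon response genes rose in 14 of 23 cases and fell in 3 (median 0.75, adjusted p = 0.032, adjusted p = 0.69 with an estimated correlation). That list was not called without AE9a high replicate 1, 5 or 6, MIG- replicate 1 or MIG+ replicate 1. Its mean in MIG- replicate 3 was 9.90, against 8.81 to 9.04 in the other controls and 9.37 to 9.93 in AE9a high. Adhesion and homing genes fell in 10 of 16 cases and rose in 5 (adjusted p = 0.03, adjusted p = 0.56 with an estimated correlation, not called without AE9a high replicate 2), with the marrow homing receptor gene Cxcr4 at -3.16. T and NK cell genes fell in 8 of 17 cases and rose in 2 (adjusted p = 0.019, adjusted p = 0.69 with an estimated correlation), and Gata3, a T cell factor, rose by 3.83. MIG- replicate 3 stood apart from the other controls on this list, at 8.73 against 7.16 to 7.34, and without it the median was -0.09 with 7 genes falling (adjusted p = 0.041). Among genes at or above the median signal the T and NK cell median was 0.07, in place of -0.47, and that call was lost. Stem and progenitor genes went both ways, 7 up and 9 down of 26, with Gata2 at 2.94, Cd34 at -2.82 and Adgrl4 at -3.84, and the list was not called (adjusted p = 0.53). The total of 8214 genes ranged from 6953 to 8244 when single arrays were left out, and 91 of 98 named calls were found in every refit. The balance of sex-linked genes differed from control as well, an item chosen after its values were seen. Xist, active in female cells, lay at 11.29 to 12.67 in the 12 AE9a arrays, 10.45 to 12.02 in the AE arrays and 9.31 to 10.80 in the controls. The Y-linked gene Eif2s3y lay at 6.26 to 10.01, 8.47 to 9.97 and 9.73 to 10.02.

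AE9a low cells differed from control by 3746 higher and 2647 lower genes, of which 447 and 654 differed at least 2-fold. Mcpt2 (5.45, limma adjusted p = 2.8e-06), Rgs13 (5.10, adjusted p = 2.47e-08), Mcpt1 (4.54), Mpped2 (4.32) and Cd59a (4.30) were highest, and Orm1 (-4.08, adjusted p = 3.98e-06), Gpr141 (-3.76), the immunoglobulin joining chain gene Jchain (-3.56), Slco4c1 (-3.40) and Igha (-3.39) lowest. Of the mast list 4 of 18 genes rose and 3 fell, with Ms4a2 at 3.67 and Prss34 at -1.85, and the list was not called (adjusted p = 0.8). Erythroid genes rose in 24 of 27 cases and fell in none (median 1.43, adjusted p = 3.2e-15, adjusted p = 0.29 with an estimated correlation, 25 rose adjusted over the list alone), with Slc4a1 at 2.60, Epb42 at 2.52 and Alas2 at 2.39. G2/M genes fell in 19 of 29 cases (median -0.29, adjusted p = 2.2e-09, adjusted p = 0.52 with an estimated correlation, 21 fell adjusted over the list alone). Late neutrophil genes fell in 14 of 22 cases (adjusted p = 8.5e-08, adjusted p = 0.52 with an estimated correlation, 18 fell adjusted over the list alone). B cell genes fell in 12 of 17 cases (adjusted p = 5.3e-07, adjusted p = 0.52 with an estimated correlation, 14 fell adjusted over the list alone). Primary granule genes fell in 3 of 12 cases (adjusted p = 0.00081, adjusted p = 0.52 with an estimated correlation). Monocyte genes fell in 6 of 26 with 1 rising (adjusted p = 0.00027, adjusted p = 0.63 with an estimated correlation). Fusion-repressed genes, some of which are also in the myeloid lists, fell in 4 of 12 (adjusted p = 0.0036, adjusted p = 0.29 with an estimated correlation). Ribosome biogenesis genes rose in 12 of 29 cases (median 0.26, adjusted p = 0.0029, adjusted p = 0.67 with an estimated correlation, 14 rose adjusted over the list alone). The list mean was 10.72 to 11.07 in AE9a low, 10.49 to 10.62 in the MIG- controls and 11.11 in the MIG+ control. Without the MIG+ array 24 of these genes rose, and without MIG- replicates 1, 2 or 3 it was 7, 4 and 5. Interferon response genes rose in 15 of 23 and fell in 1 (median 0.74, adjusted p = 0.0062, adjusted p = 0.65 with an estimated correlation, not called without MIG+ replicate 1). Camera called 7 further lists of lower genes at adjusted p of 0.02 to 0.035 (0.29 to 0.66 with an estimated correlation). These held genes high in leukaemia with the translocation, Hoxa and Meis, dendritic, T and NK cell, NF-kB, cholesterol synthesis and adhesion genes. Without MIG- replicate 3 the leukaemia, T and NK cell, NF-kB and dendritic lists were not called, nor was the dendritic list without AE9a low replicate 3 or 4. The Hoxa list was not called without AE9a low replicate 6, MIG- replicate 1 or MIG+ replicate 1, nor the cholesterol list without MIG- replicate 2. The T and NK cell median turned from -0.38 to 0.12 among genes at or above the median signal. The total of 6393 genes ranged from 4847 to 7178 when single arrays were left out, and 71 of 85 named calls were found in every refit.

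AE high cells, with 2 arrays, had 2420 higher and 1771 lower genes than control, of which 625 and 403 differed at least 2-fold. Mast cell genes again stood highest, with Tph1 at 6.22 (limma, adjusted p = 3.31e-05), Mcpt4 at 6.01, Mcpt2 at 5.38, Cd200r3 at 5.32 and Cma1 at 5.27. Igha (-4.50), Orm1 (-4.42), Nxpe2 (-4.36), Ly6g (-4.09) and Slco4c1 (-4.04) were lowest. Of the mast cell, basophil and eosinophil list 11 of 18 genes rose and none fell (median 1.48, adjusted p = 5.9e-07, adjusted p = 0.21 with an estimated correlation, 12 rose adjusted over the list alone), with Tpsb2 at 5.09. Stem and progenitor genes rose in 12 of 26 cases and fell in 2 (median 0.75, adjusted p = 3.5e-06, adjusted p = 0.22 with an estimated correlation, 14 rose and 3 fell adjusted over the list alone). Slamf1 stood at 3.67, Tek at 3.20 and Gata2 at 2.76. S-phase genes fell in 20 of 27 cases (median -0.43, adjusted p = 5.9e-11, adjusted p = 0.4 with an estimated correlation, 24 fell adjusted over the list alone). B cell genes fell in 11 of 17 cases (adjusted p = 2.4e-06, adjusted p = 0.61 with an estimated correlation, 13 fell adjusted over the list alone). Late neutrophil genes fell in 6 of 22 (adjusted p = 0.00011, adjusted p = 0.73 with an estimated correlation, 9 fell adjusted over the list alone). Interferon response genes rose in 10 of 23 cases (adjusted p = 2e-05, adjusted p = 0.61 with an estimated correlation, 12 rose adjusted over the list alone). Cholesterol synthesis genes fell in 10 of 16 with 1 rising (median -0.37, adjusted p = 0.0048, adjusted p = 0.36 with an estimated correlation). Erythroid genes rose in 8 of 27 cases and fell in 5, Hemgn by 1.85 and Tfrc by 1.59 among the latter, and the list was not called (adjusted p = 0.43). G2/M genes fell in 6 of 29 cases (adjusted p = 0.00034, adjusted p = 0.73 with an estimated correlation, not called without AE high replicate 1). The monocyte, dendritic, T and NK cell and megakaryocyte lists were called at adjusted p of 0.033 to 0.047 (0.22 to 0.77 with an estimated correlation), and none of these 4 without AE high replicate 2. The megakaryocyte list was also lost without AE high replicate 1 or MIG+ replicate 1, and the monocyte list without MIG- replicate 2 or 3. The total of 4191 genes was 1940 without AE high replicate 1 and 2464 without AE high replicate 2, and 50 of 80 named calls were found in every refit. It was 2655 in a fit of these 2 groups alone.

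AE low cells, also with 2 arrays, had 2795 higher and 1283 lower genes than control, of which 406 and 283 differed at least 2-fold. The highest were Mpped2 (4.69), Cd59a (4.19), Cd200r3 (4.10), Tph1 (4.02) and Mcpt2 (3.93), and the lowest Igha (-4.38), Nxpe2 (-3.37), Jchain (-3.23), the immunoglobulin gene Ighg3 (-3.01) and Orm1 (-2.95). Of the 74 named genes past the threshold here, 18 passed it without each array in turn and 56 did not. Erythroid genes rose in 24 of 27 cases and fell in none (median 1.35, limma camera adjusted p = 6.9e-18, adjusted p = 0.49 with an estimated correlation, 26 rose adjusted over the list alone). Ribosome biogenesis genes rose in 16 of 29 cases (median 0.49, adjusted p = 5e-09, adjusted p = 0.61 with an estimated correlation, 23 rose adjusted over the list alone). Their list mean was 11.15 to 11.23 in AE low and 11.11 in the MIG+ control, against 10.49 to 10.62 in the MIG- controls. Interferon response genes rose in 9 of 23 (median 0.78, adjusted p = 7.1e-05, adjusted p = 0.61 with an estimated correlation, 11 rose adjusted over the list alone). B cell genes fell in 4 of 17 cases (median -1.37, adjusted p = 2.6e-05, adjusted p = 0.61 with an estimated correlation, 5 fell adjusted over the list alone). Late neutrophil genes fell in 2 of 22 cases (median -1.35, adjusted p = 0.00087, adjusted p = 0.61 with an estimated correlation), a call lost without AE low replicate 2. The primary granule, monocyte, G2/M and adhesion lists were lower at adjusted p of 0.002 to 0.031 (0.61 to 0.64 with an estimated correlation), and none of these 4 was called without AE low replicate 2. The T and NK cell and the Hoxa and Meis lists were lower too (adjusted p = 0.0079 and 0.0096, adjusted p = 0.61 with an estimated correlation for both), the latter not without AE low replicate 1. Mast list genes rose in 5 of 18 cases and fell in 1, and the list was not called (adjusted p = 0.22). The total of 4078 genes was 909 without AE low replicate 2 and 816 in a fit of these 2 groups alone.

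Between constructs, averaged over both gates, 2335 genes were higher and 1461 lower in AE9a than in AE, of which 48 and 177 differed at least 2-fold. Rgs13 (2.57, limma adjusted p = 1.41e-05), Slc6a20a (2.31), Radx (2.19), Apobec2 (1.96) and the fatty acid desaturase gene Scd1 (1.96) were highest in AE9a. The proenkephalin gene Penk (-2.69), Ctla2a (-2.45), Stat4 (-2.45), the melanocortin receptor gene Mc5r (-2.20) and Plxdc2 (-2.17) were lowest. Stem and progenitor genes were lower in AE9a in 13 of 26 cases and higher in none (median -0.36, adjusted p = 2.1e-06, adjusted p = 0.38 with an estimated correlation), with Angpt1 at -2.07 and Meis1 at -1.30. The gap lay mostly in the high gate, with list means of 8.60 in AE9a high against 9.57 in AE high, and 8.64 in AE9a low against 8.74 in AE low. Meis1 stood at 7.37 against 9.74 and at 7.23 against 7.47. Mast list genes were lower in 6 of 18 cases (median -0.73, adjusted p = 0.0014, adjusted p = 0.42 with an estimated correlation), with Cyp11a1 at -1.83, Mcpt4 at -1.82 and Tpsb2 at -1.58. Erythroid genes were higher in 12 of 27 cases (median 0.40, adjusted p = 0.00021, adjusted p = 0.77 with an estimated correlation, 15 higher adjusted over the list alone), with Rhd at 1.16 and Slc4a1 at 1.12. In the low gate the erythroid list mean was 11.29 for both constructs, and in the high gate 10.85 in AE9a against 9.95 in AE. Primary granule, late neutrophil, monocyte, ribosome biogenesis and fusion-repressed genes were lower in AE9a by camera at adjusted p of 0.00034 to 0.041 (0.43 to 0.77 with an estimated correlation), with 2, 0, 2, 0 and 1 members past limma's threshold. The fusion-repressed list shares members with the myeloid lists named here. The late neutrophil, monocyte and ribosome lists were not called without AE low replicate 1, nor the ribosome list without AE high replicate 2. The fusion-repressed list was not called without AE9a high replicate 3, AE9a low replicate 3 or 4, AE high replicate 1 or AE low replicate 1. Runx1 was higher in AE9a by 0.38 (limma, adjusted p = 0.0373), while Runx1t1 did not pass (0.14, adjusted p = 0.297). AE9a is the shorter splice form, and which part of each transgene the Runx1t1 probes bind could not be checked. The Runx1t1 signal therefore does not compare transgene levels between the constructs. The labels gave no batch, so a batch that follows the construct cannot be told apart from it. The total of 3796 genes was 777 without AE high replicate 1, 909 without AE low replicate 1 and 1945 without AE high replicate 2, and 28 of 59 named calls were found in every refit. It was 1687 among genes at or above the median signal, and it was also lower with the replicate number as a random block, as given further below.

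The overlap of these lists was counted gene by gene. Of the genes higher in the high gate 270 were called for both AE9a and AE, and of those lower 503. A further 4 were called in opposite directions. Independent lists would be expected to share 37.7 higher and 55.4 lower genes. These lists are not independent, because the fit for AE high versus AE low took its spread from all arrays, including the AE9a ones. Genes of low spread can pass in both, so the expected numbers do not test for a shared response. Slamf1, Jup and Ubash3b rose and Hemgn, Ccne1 and Rrm2 fell in both comparisons. Across genes, which are not independent replicates, the 2 high-minus-low differences correlated with r = 0.41. For comparisons that share the 4 controls, AE9a high and AE high had r = 0.78 against 0.45 in 20 simulations of unchanged groups, a covariance of 0.278 against 0.011, and r = 0.71 to 0.74 when the controls were split between them. The sign was the same for 65.8% of genes, against 64.9% in those simulations. They shared 1813 higher and 1348 lower genes, and 76 were called in opposite directions. AE9a low and AE low had r = 0.92 against 0.45, a covariance of 0.209 against 0.011, r = 0.81 to 0.85 with split controls and the same sign for 72.4% of genes against 64.7%. They shared 2081 higher and 1142 lower genes, with 1 called in opposite directions. Shared controls make such lists overlap by themselves, and no expected number for that was computed.

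The MIG+ control array was set beside the 3 MIG- arrays without a test, since a single array has no spread. Its late neutrophil list mean was 11.31, against 12.32 to 12.58 in the MIG- arrays, and its erythroid mean 10.48 against 9.68 to 9.86. Ribosome biogenesis genes averaged 11.11 against 10.49 to 10.62, and monocyte genes 9.27 against 9.51 to 9.96. On the MIG+ array 18 genes lay more than 1 log2 unit above every MIG- array and 216 more than 1 unit below.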

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

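In this part only the test of scaling on the neutrophil genes was chosen after the result was seen. A single array stood apart from the others of its group, by the ratio of its gap to the range, in 14 of 162 groups of values. Chance alone gives about 1 in 20, here 8.1. The limits were Dixon's tabulated ones for groups of 4 and of 6 arrays.

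In AE9a high, replicate 3 was lowest for the dendritic and antigen presentation list (7.46 against 7.61 to 7.68, ratio 0.69), the G2/M list (11.01 against 11.19 to 11.27, ratio 0.7) and H2-Aa (6.81 against 7.69 to 7.98, ratio 0.75). Replicate 5 was lowest for CDK inhibitors (8.89 against 9.01 to 9.04, ratio 0.75). Replicate 6 was highest for NF-kB and inflammation genes (8.01 against 7.68 to 7.73, ratio 0.87) and for Gria3 (7.92 against 6.26 to 6.80, ratio 0.67). In AE9a low, replicate 2 was highest for B cell genes (10.02 against 6.86 to 8.04, ratio 0.63) and BCL2 family genes (9.05 against 8.87 to 8.91, ratio 0.8), and replicate 6 lowest for Meis2 (6.83 against 8.47 to 9.33, ratio 0.66).

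Among the controls, MIG- replicate 3 was highest for T and NK cell genes (8.73 against 7.16 to 7.34, ratio 0.89) and lowest for the mast cell list (8.02 against 8.50 to 8.59, ratio 0.84) and for Prss34 (9.25 against 10.94 to 11.16, ratio 0.88). The MIG+ array was highest for stem and progenitor genes (9.14 against 8.70 to 8.73, ratio 0.94) and lowest for CDK inhibitors (8.50 against 9.02 to 9.04, ratio 0.96). It is the single control of its title, so no biological explanation was tested.

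The high-minus-low difference differed between AE9a and AE for 235 genes, by the interaction test. By the same test the stem and progenitor list differed with a median of -0.71, and the list of genes high in leukaemia with the translocation with a median of -0.3. These values rest on 2 arrays per AE arm. The count was 62 without AE high replicate 1, 72 without AE low replicate 1 and 386 without AE high replicate 2, and the stem and progenitor median was -0.34 without AE low replicate 1.

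Neutrophil genes differed widely between arrays of 1 AE9a arm, with a within-arm SD of the late neutrophil list mean of 1.11 log2 units. Scaling of the arrays moves genes of similar signal alike. In the deposited values 1000 random lists matched on mean signal had a median within-arm SD of 0.04 and a highest of 0.25. Little difference in scale was thus left between the arrays, but RMA had already set them to about the same distribution. Such lists could therefore hardly spread, and they do not test what that scaling did to the neutrophil genes. A shared animal or pool behind the high and low array of 1 number stays open, because the list means of same-numbered arrays correlated with r = 0.51 over 6 pairs (exact permutation p = 0.32, Spearman's rho 0.66, p = 0.18). A differing share of granulocyte precursors was not tested and may also explain the spread. The c-Kit sort should remove mature neutrophils, yet the late neutrophil list averaged 12.14 in the sorted controls, so their carry-over was not excluded.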

How the results depend on the processing

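The covariates and the fit without 3 arrays were chosen after the results were seen. Of 151 recomputed counts of genes, 124 lay within 1.5 times the reported one. Of 4374 recomputed list tests 3980 kept their direction and side of the threshold, 269 lost the call, 120 gained it and 5 turned, and of 11481 recomputed named genes 10287, 1103, 86 and 5 did. The list tests include lists that were never called and refits that share most of their arrays. With an estimated correlation 90 list calls were lost. Only 4 of 9 calls for AE high versus AE low stayed, and 2 of 17 for the difference between the constructs. In every other comparison all list calls were lost.

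Leaving out single arrays gave 960 to 2799 genes for AE9a high versus AE9a low, 314 to 1756 for AE high versus AE low, 62 to 386 for the difference between these, 6953 to 8244 for AE9a high and 4847 to 7178 for AE9a low versus control, 1940 to 4849 for AE high and 909 to 5199 for AE low versus control, and 777 to 5226 for AE9a versus AE. The lowest counts for comparisons with AE came without AE high replicate 1 or, for AE low versus control, AE low replicate 2. An arm then holds 1 array, which is assumed to vary like the other groups.

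A fit of only the groups compared gave 0 genes for AE high versus AE low (limma, 4083 at an unadjusted p under 0.05), 360 for the difference between constructs, 2655 for AE high versus control and 816 for AE low versus control, with fewer arrays to estimate the spread. The filter at the median signal gave 84 for the difference and 1687 for AE9a versus AE, with fewer genes tested, and array weights gave 482 for the difference. For AE9a high versus AE9a low the mast list covariate gave 0 genes (915 unadjusted), and since it correlated with the arm at 0.88 little of the arm's difference was left to test. The neutrophil covariate gave 1333, and 1194 genes passed without AE9a high replicate 6 and AE9a low replicates 1 and 3. Median centring gave 1084 higher and 540 lower genes there (66.7% higher against 54.4%).

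Values that turned sign were the late neutrophil list with its own mean as covariate (0.02), and, with the mast covariate, Mcpt4 (-0.59), Tpsb2 (-0.49), Cma1 (-0.64) and the mast list (-0.1), as taking out a list's own mean does. Under the filter at the median signal, on fewer genes, the T and NK cell median was 0.07 for AE9a high and 0.12 for AE9a low versus control, and for AE high versus control it stayed negative at -0.15 while camera's direction turned. Runx1 in AE low versus control was -0.13 without AE low replicate 2 and 0.33 without AE low replicate 1, and Runx1t1 in AE9a versus AE was 0 without AE low replicate 1 and 0.28 without AE low replicate 2. For all other changes the cause was not tested.

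The replicate numbers were checked for pairing. After each gene's arm mean was taken out, same-numbered AE9a arrays correlated across genes with -0.26, -0.24, 0.58, 0.57, 0.19 and 0.73. So 4 of 6 lay over 0.1, and 5 of 12 arrays correlated best with their own number in the other arm. Xist matched between same-numbered arrays (r = 0.94, exact permutation p = 0.0056) more closely than Y-linked genes (r = 0.72, p = 0.11), a hint from the data and not the design, and Xist also differed between AE9a arrays (11.29 to 12.67) and controls (9.31 to 10.80). With the number as a block the counts were 2624 for AE9a high versus AE9a low (1685 of them among the 1840), 2922 for AE high versus AE low and 283 for the difference. As a random block they were 8200, 6374, 4117 and 4012 for the comparisons with control, in the order given above, and 1529 for AE9a versus AE. List tests were not run under the random block.

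Of 100 splits of the 12 AE9a arrays into 6 and 6, 2 gave at least 1840 genes, the real one included. So large a count was uncommon among splits, which treat the arrays as independent, and the labels did not state that they are. The highest other split gave 2208 and swapped AE9a high replicate 6 with AE9a low replicate 3, with late neutrophil means of 9.11 and 10.8 on its sides, which points to a structure of the samples beyond the gate. For AE9a high versus control 1 of 100 splits, the real one with 8214 genes, reached its count (highest other 3954), and for AE9a low versus control 1 of 100 with 6393 (highest other 4904). The same assumption of independent arrays applies to these splits. Array signal limits dim genes, since RMA values compress changes near background.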

Other observations

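The 4 lists in the next 2 paragraphs, the tests of dilution and of scaling for the mast cell and cell cycle genes, and the use of covariates were chosen after the results were seen. The tests of covariates on the cell cycle genes and of Runx1t1 against mast cell genes were stated before their own results were seen.

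Genes of serotonin and histamine handling were listed after several had been seen among the highest changes, and were not tested as a set. Of 8 such genes, all 8 rose in AE9a high against control (median 3.43), 5 in AE9a low (median 1.66), 7 in AE high (median 3.95) and 4 in AE low (median 2.23), and none fell. In AE9a high, Tph1, which starts serotonin synthesis, rose by 4.55 log2 units (limma, adjusted p = 1.49e-05), Ddc, which completes it, by 4.61 (adjusted p = 9.64e-08), the vesicle transporter gene Slc18a2 by 3.23 (adjusted p = 1.56e-05), and the histamine receptor gene Hrh4 by 4.35 (adjusted p = 7.85e-06). From AE9a low to AE9a high 3 of the 8 rose, namely Slc18a2 by 1.72, Maob by 1.82 and the histamine-making enzyme gene Hdc by 1.01 (adjusted p = 0.0148). Of 10 mast granule protease genes 8 rose and 2 fell in AE9a high against control (median 2.98), and 5 rose from AE9a low to high. Of 10 genes that lean to basophils 5 rose and 1 fell in AE9a high against control (median 0.72), with Cd200r3 at 5.24 and Il4 at 1.44 against the basophil protease gene Mcpt8 at -1.14 (adjusted p = 0.239).

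Plasma cell genes went the other way against control. Of 10 such genes 9 fell in AE9a high (median -1.9), 6 in AE9a low (median -1.01), 5 in AE high with 1 rising (median -1.65) and 6 in AE low (median -0.93). Igha averaged 7.09 in AE9a high, 8.16 in AE9a low, 7.04 in AE high and 7.16 in AE low, against 11.54 in control, and Jchain 6.41, 6.64, 6.63 and 6.97 against 10.20. From AE9a low to AE9a high the median was -0.22, and Igha stood at -1.07 (adjusted p = 0.183). A c-Kit sort should remove mature plasma cells, yet the sorted controls held the Igha and Jchain signals given above. Carry-over of such cells was therefore not excluded. The first principal component held 61.1% of the variance, with the MIG- controls at 61.2 to 64.2, the MIG+ control at 43.1, AE9a high between -44.4 and -5.4, AE9a low between -42.5 and 20.9, with replicates 3 and 4 at -42.5 and -35.9 among AE9a high, and the AE arrays between -15.9 and 25.8.

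The rise of mast cell genes from AE9a low to AE9a high may reflect a larger share of mast cells in the high gate, which the c-Kit sort keeps, a higher expression per cell, or both, and bulk arrays cannot separate these. The megakaryocyte and erythroid list means moved apart by 0.72 log2 units (within-arm SD 0.10 and 0.24, exact permutation p = 0.0022, the smallest the 924 splits can give). This gap cannot decide on a share that dilutes every other cell type alike. The opposite moves of these lists were known before the test, and whether mast cells express megakaryocyte list genes was not tested. Single genes show less of this gap, with 4 of 17 megakaryocyte genes rising and 1 falling, and 10 of 27 erythroid genes falling, and neither list was called with an estimated correlation (adjusted p = 0.21 and 0.34). Under median centring 10 of 18 mast list genes rose. Array medians already lay between 7.31 and 7.43, so this centring could change little and does not test an effect of scaling. What RMA itself did to the values was not tested. A graded response to the transgene within an arm stays open, because Runx1t1 and the mast list mean correlated with r = 0.4 in AE9a low (exact permutation p = 0.43, rho 0.26, p = 0.66, r = 0.24 without the 2 farthest arrays) and 0.28 in AE9a high (p = 0.62, rho 0.14, p = 0.8, r = -0.35 without them), with an adjusted p of 0.62 for both relations.

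The rise of G2/M genes beside the fall of S-phase genes from AE9a low to AE9a high is a second pattern to follow up. The hypothesis is a cell cycle distribution that differs between the gates. G2/M list means were 11.19 in AE9a high, 10.93 in AE9a low and 11.21 in control, so AE9a high did not lie above control. S-phase list means were 10.63, 10.92 and 10.88 in the same order, so there AE9a low lay near control. The difference between the G2/M and S-phase list means, from which a scaling factor cancels, moved by 0.56 (exact permutation p = 0.0022). The opposite moves of these lists were known before this test, so its outcome adds little to them. With the neutrophil list mean as a covariate this difference was 0.55 (95% interval 0.47 to 0.64), and with the mast list mean 0.54 (0.37 to 0.7). The neutrophil list mean thus did not account for it. The mast mean correlated with the arm at 0.88, so that fit cannot decide. A list mean is no measured share of cells, and the erythroid list, whose mean moved by -0.45, was not tried as a covariate. Differing shares of cell types therefore stay open. Larger or later-cycle cells may hold more GFP and so enter the high gate more often, an explanation that these data cannot test. In AE high against AE low S-phase genes fell as well, but no G2/M gene passed limma's test, with G2/M list means of 10.99 and 11.05. RNA levels of phase genes are no count of cells in a phase.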
